A study of Mus musculus with 30 samples.

How the data were processed

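The series profiled 3T3-L1 cells, a mouse fibroblast line that turns into fat cells when treated with hormones. Per the labels' protocols, cells past confluence received 1 μM dexamethasone (a synthetic glucocorticoid), 0.5 mM isobutylmethylxanthine (IBMX, which raises cyclic AMP), 1 μg per ml insulin and 10% fetal calf serum. They were harvested 4 h later. Of 30 labelled samples, 9 had a file used here: chromatin immunoprecipitation with sequencing (ChIP-seq) of the transcription factors ATF2, ATF7, cJun, FOSL2, JunB, KLF4, KLF5, VDR and RXR, with 1 library per factor. The other 21 samples were not analysed here.

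The authors deposited, for each factor, a list of genomic intervals in the mouse build mm9, with chromosome, start and end as the only 3 columns. Per the submitters' processing notes, FastQC, Bowtie, HOMER and mm9 were used. Their versions, their roles and the threshold for a peak are not given in the sources used here. The lists held no score, no read number and no control value, so the depth of each library is unknown and sites could not be ranked by signal. The sequencing depth and the antibody both influence how many sites a list holds.

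Every deposited interval was 400 bp long. The 9 lists were subsets of 1 common set of 34726 intervals: a site shared by several lists had the same coordinates in each, and the midpoints of different intervals lay at least 201 bp apart, so that neighbouring 400 bp intervals could overlap. The order of shared intervals was identical in 36 of 36 pairs of lists. How the common set was made is not given in the sources used here. Sharing between factors therefore means listing of the same interval. Distances between the midpoints of shared sites were fixed by this construction (median 0 bp in 36 of 36 pairs) and carry no information on the spacing of factors.

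Intervals on chromosomes 1 to 19 and X were kept, which left 34724 intervals; 2 intervals on chromosome Y were left out. Each interval was replaced by a 200 bp window at its midpoint, and windows overlapping by at least 1 bp were merged into regions. A region listed for 5 or more of the 9 factors was called a hotspot. Hotspots within 10 kb of each other were joined into clusters. The lists of MED1, which could define super-enhancers, were not used here, and clusters are not called super-enhancers. Coordinates are given 1-based in mm9. With no mm9 genome or annotation used here, no gene is named near a region and no motif was counted.

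Shares of sites carry exact Clopper-Pearson 95% intervals, which cover counting error only. Differences of shares and odds ratios carry 95% intervals from a jackknife that left out each of 20 chromosomes in turn, with the t distribution on 19 degrees of freedom. With 1 library per factor, none of these errors covers variation between cultures or antibodies. Lists of equal length came from a single random draw of sites, and no interval covers variation between such draws. The draw removes most sites from the longest lists, which by itself lowers their shared sites. It does not show what libraries of equal depth would have listed. Chance values for sharing and hotspots came from 1000 circular shifts of the lists within each chromosome, one-sided. Because shifted lists almost never meet on a common set of intervals, a stricter value was added after the data were examined: each list's sites were reassigned at random among the common intervals of each chromosome, 1000 times. For clusters, shifting all hotspots together keeps every distance and tests nothing, so the same number of sites per chromosome was drawn at random from the common set instead.

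For each of 36 pairs of factors, a Mantel-Haenszel odds ratio compared joint listing with separate listing among regions bound by the same number of the other 7 factors (1 to 7). Values were adjusted by the Benjamini-Hochberg method over 36 pairs with a threshold of 0.05. A logistic model with the other 7 factors as separate terms was the alternative. The logistic and the unadjusted odds ratios also left out regions with none of the other 7 factors. An exact one-sided permutation test over all assignments of the 9 factors to families of 5, 2 and 2 asked whether pairs within a DNA-binding family had higher odds ratios. The families were bZIP (ATF2, ATF7, cJun, FOSL2 and JunB), KLF (KLF4 and KLF5) and nuclear receptors (VDR and RXR). Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

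The calculations were tested on simulated lists. Independent lists gave 0 of 36 called pairs. A planted odds ratio of 4 was recovered with a mean of 3.98 over 20 draws, and the 95% interval held the planted value in 19 of them. Lists that shared 1 axis of general occupancy and nothing else gave stratified odds ratios of 1.56 to 1.84 and logistic odds ratios of 1.57 to 1.86, and all 36 pairs were called higher. This simulation held 60000 sites and gave every factor the same dependence on the axis. The dependence was set to give about the observed number of listed regions, and the numbers of factors per region were not matched. With such an axis the planted odds ratio of 4 came out at 6.03 (95% interval 5.69 to 6.39). An odds ratio above 1 thus does not by itself set a pair apart from the others, and odds ratios beside such an axis are inflated. Random values passed the family test in 6% of 100 draws.

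Named regions followed a rule written before the data were examined: the 10 regions with most factors, the 5 clusters with most hotspots, the 5 pairs with the highest and the 5 with the lowest odds ratio, and the dimer and family pairs VDR-RXR, KLF4-KLF5, ATF2-ATF7, cJun-JunB, cJun-FOSL2 and FOSL2-JunB. All 504 regions with 9 factors tied and were taken by position. The best-scoring site of each list, also part of the rule, was not reported for lack of scores. The alternatives tried were the deposited intervals, windows of 100 bp and 500 bp, an overlap of at least 50% of the window, equal list lengths by random draw, 4 or 6 factors per hotspot, each list left out, a count of factors around each midpoint in place of merged regions, joining within 5 kb or 20 kb, every chromosome, and the unadjusted and logistic odds ratios. The shares of each list in hotspots, the makeup of hotspots, the partner shares of FOSL2, VDR and KLF5, 8 differences of such shares and results without 3 dense blocks of sites on chromosome 10 were added after the data were examined. So were the family tests with unadjusted and with logistic odds ratios.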

Results

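Binding of 9 transcription factors was mapped by ChIP-seq in 3T3-L1 pre-adipocytes 4 h after adipogenic induction. ATF2, ATF7, cJun, FOSL2 and JunB belong to the bZIP proteins, which bind DNA as dimers; cJun, JunB and FOSL2 are AP-1 subunits. KLF4 and KLF5 are zinc-finger factors of the Krüppel-like family. VDR is the vitamin D receptor, and RXR, the retinoid X receptor, is its heterodimer partner. Each factor had 1 library and no replicate, and the depth of the libraries is unknown. The lists held between 5876 sites for KLF4 and 17120 for KLF5. In between were cJun with 6176 sites, FOSL2 with 6284, ATF7 with 7375, JunB with 10082, ATF2 with 11547, VDR with 11796 and RXR with 12082. Together they covered 34724 regions on chromosomes 1 to 19 and X.

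The series title names hotspots, regions where many factors bind, and the first comparison asked how often the factors met. A single factor was listed at 15048 regions (43.3%), and 5 or more of the 9 factors were listed at 5623 regions, or 16.2% (95% exact interval 15.8 to 16.6). These hotspots held 40.0% of all list entries. All 9 factors were listed at 504 regions, where random reassignment of sites among the common intervals gave a mean of 0.229 and at most 2. At the other end, reassignment gave a mean of 6091 regions with a single factor. Reassignment keeps the sites to the common intervals, so the excess of single-factor regions holds against this chance value alone; shifted lists hardly met at all. Random reassignment gave 2562 ± 37.6 hotspots (SD of 1000 draws) and at most 2676, so the observed number was 2.19-fold higher (permutation p = 0.001, one-sided). The excess lay in regions with 6 or more factors. Regions with exactly 5 factors numbered 2018, against a reassigned mean of 1995 and at most 2114. Circular shifts of the lists gave 0 hotspots in each of 1000 draws (permutation p = 0.001, one-sided). In both tests this p is the smallest that 1000 draws can give. Hotspots rose to 8378 when 4 or more factors were required and fell to 3605 when 6 or more were required. They fell to 1964 when all lists were thinned to the length of the shortest.

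**Figure D1:**
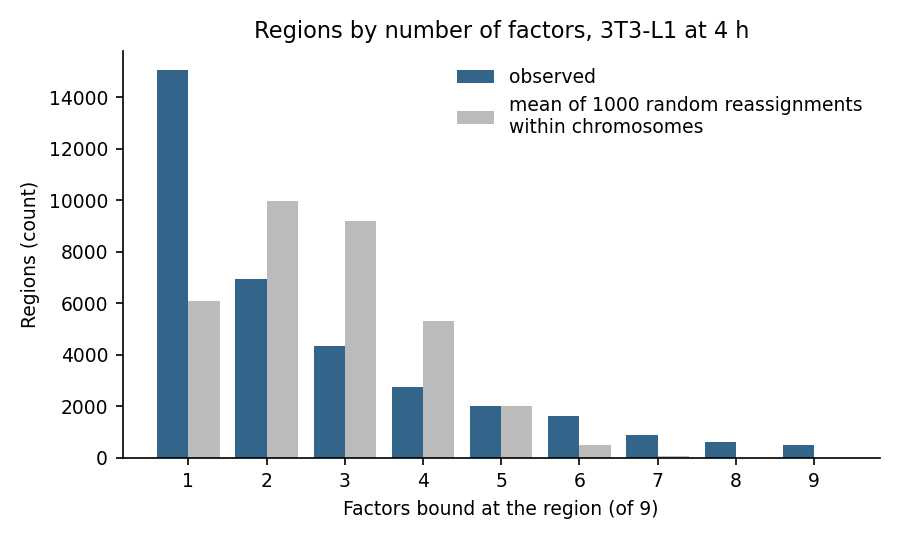
Number of regions (vertical axis) by number of factors listed, 1 to 9 (horizontal axis), as observed and as the mean of 1000 random reassignments within chromosomes. Regions with 1 factor and with 6 or more exceeded the reassigned means, and regions with 2 to 4 factors fell below them. Regions with 5 factors were close to the reassigned mean (2018 against 1995).

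The first 10 of the 504 regions with all 9 factors, in order of position, lay on chromosome 1 (mm9, each 400 bp long). They were 16218432 to 16218831, 20059804 to 20060203, 40228933 to 40229332, 40415633 to 40416032, 40450029 to 40450428, 40492889 to 40493288, 45412683 to 45413082, 63840927 to 63841326, 79819394 to 79819793 and 84403451 to 84403850. What the annotation places at these positions was not analysed here.

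The factors differed in how much of their binding lay in hotspots. KLF4 and cJun had the highest shares, 60.1% (95% exact interval 58.8 to 61.3) and 58.5% (57.2 to 59.7). JunB had 45.5% (44.5 to 46.4), FOSL2 44.0% (42.8 to 45.3), RXR 40.7% (39.9 to 41.6) and VDR 39.9% (39.1 to 40.8). ATF7 had 35.4% (34.3 to 36.5), KLF5 30.7% (30.0 to 31.4) and ATF2 28.8% (28.0 to 29.7). The share of sites bound by no other factor was lowest for KLF4 (5.07%) and cJun (5.94%) and highest for KLF5 (24.0%) and ATF2 (28.1%). The AP-1 subunits cJun and FOSL2, with lists of similar length, differed by 14.4 points (95% jackknife interval 9.62 to 19.3), and VDR exceeded ATF2 by 11.1 points (8.65 to 13.5). KLF4 and cJun were not told apart (difference 1.61 points, interval -0.708 to 3.92). All shares fell when the lists were thinned at random to the length of the shortest: KLF4 had 25.9%, cJun 24.8%, FOSL2 23.1%, JunB 22.5%, RXR 20.0%, ATF7 19.8%, VDR 19.3%, ATF2 17.1% and KLF5 16.3%. The shortened lists came from a single random draw of sites, and the intervals do not cover variation between draws. Thinning lowers these shares by construction, so smaller differences at that length do not show that list length made the differences. At that length cJun and FOSL2 were not told apart (difference 1.63 points, interval -1.36 to 4.63), and VDR exceeded ATF2 by 2.14 points (0.354 to 3.94). JunB and FOSL2 were not told apart either (difference -0.647 points, -3.37 to 2.07), and without dense blocks of sites on chromosome 10 FOSL2 had 45.9% and JunB 45.1%.

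**Figure D2:**
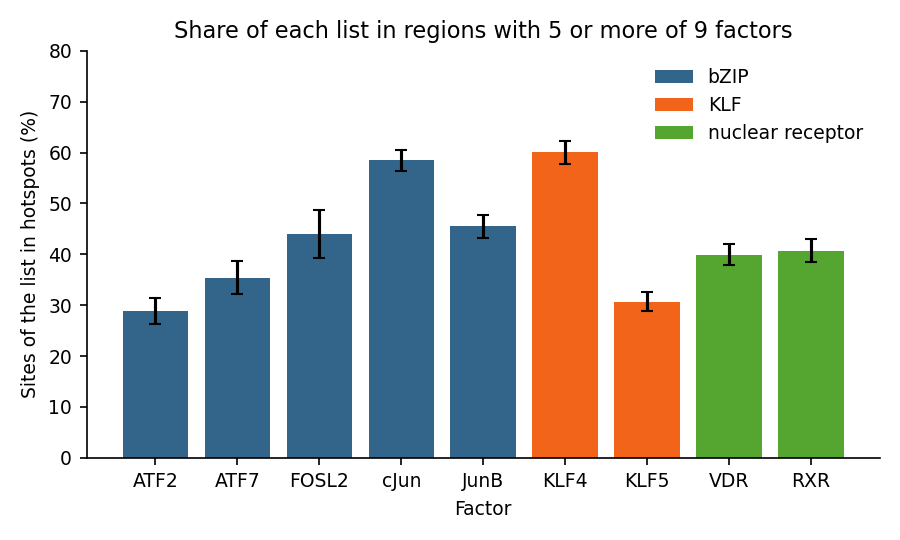
Share of each factor's sites in hotspots (percent), coloured by DNA-binding family; error bars are 95% intervals from leaving out each chromosome in turn. KLF4 and cJun reach 60.1% and 58.5%, and ATF2 has the lowest share with 28.8%.

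Seen from the hotspots, KLF5, the factor with the longest list, was listed at 93.5% of them. RXR was listed at 87.5%, VDR at 83.8% and JunB at 81.5%. cJun, KLF4 and ATF2 were listed at 64.2%, 62.8% and 59.2%, and FOSL2 and ATF7 at 49.2% and 46.4%. Both nuclear receptors were present at 77.7% of hotspots. All 3 families met at 89.9%, and 75 hotspots (1.33%) held bZIP factors alone. Equal chances for every combination of the same number of factors would give 82.7% and 16.0 hotspots. These values take no account of list length, although KLF5, RXR and VDR had the longest lists. The order of the factors changed when all lists were thinned at random to the length of the shortest. KLF4 was then the most frequent member (77.4%), followed by cJun (74.1%), FOSL2 (69.2%) and JunB (67.3%), and KLF5 was the least frequent (48.7%). Such thinning leaves the shortest list, KLF4, whole and takes most from the longest, KLF5, which by construction moves them up and down. This order is thus not one corrected for list length.

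The next question was which factors shared sites with each other. Over the 72 ordered pairs, the share of a factor's sites listed for another factor ranged from 17.5% (ATF2 sites with cJun) to 86.4% (KLF4 sites with KLF5), with a median of 34.1%. Circular shifts gave a mean share of at most 0.289% for any ordered pair, but this is near 0 by construction, since shifted lists hardly meet on common intervals. Reassignment among the common intervals gave mean shares of 17.0% to 49.5% (median 29.2%), and 27 of 36 pairs lay above all 1000 draws. Below all draws lay 4 pairs: ATF2 sites shared 44.0% with KLF5 (reassigned mean 49.3%), 29.8% with RXR (34.5%) and 27.6% with VDR (33.7%), and ATF7 sites shared 46.7% with KLF5 (49.1%). The other 5, among them ATF2-cJun (reassigned mean 17.7%), lay within the draws. No common interval lacked a listed factor, whereas reassignment left some with none. This construction alone can lower the observed sharing against the draws, so the pairs below all draws do not by themselves show avoidance. Among known partners and close relatives, JunB was listed at 80.1% of cJun sites (95% exact interval 79.1 to 81.1), and cJun at 49.0% of JunB sites. RXR was listed at 67.1% of VDR sites and VDR at 65.5% of RXR sites. ATF2 was listed at 65.9% of ATF7 sites, and ATF7 at 42.1% of ATF2 sites. KLF4 was listed at 29.7% of the more numerous KLF5 sites. Several shares between families were above that of RXR sites with VDR: RXR was listed at 71.0% and VDR at 69.0% of KLF4 sites, and KLF5 at 69.7% of RXR, 66.8% of VDR and 66.0% of cJun sites. With all lists at the length of the shortest, the median share was 23.6%.

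Because hotspots raise the sharing of every pair, pairs were then compared among regions bound by equal numbers of the other 7 factors. cJun-JunB had the highest odds ratio, 19.3 (95% jackknife interval 17.4 to 21.4). It was followed by VDR-RXR with 14.7 (13.6 to 15.9), ATF2-ATF7 with 14.2 (13.1 to 15.5), KLF4-KLF5 with 10.2 (8.68 to 12.0) and KLF5-RXR with 6.60 (6.11 to 7.14). These 5 pairs were above 1 on 20 of 20 chromosomes. In a logistic model with the other factors as separate terms, the odds ratios were 19.4, 9.86, 11.6, 7.95 and 4.45. The sizes and their order changed when all lists were thinned at random to the length of the shortest. The stratified odds ratios were then 5.98 for cJun-JunB, 5.17 for ATF2-ATF7, 2.93 for VDR-RXR, 2.38 for KLF4-KLF5 and 1.87 for KLF5-RXR. All 5 were still called higher, but VDR-RXR then stood below ATF2-ATF7, ATF7-FOSL2 (4.75), ATF2-FOSL2 (3.65), KLF4-VDR (3.20) and KLF4-RXR (3.08), and cJun-KLF4 (2.61) and FOSL2-JunB (2.48) stood above KLF4-KLF5. Random removal of sites can itself lower an odds ratio, and the lists did not lose equal parts. The changed sizes and order are thus not corrected for list length. In all, 21 of 36 pairs were called higher, 11 lower and 4 neither. Without stratification all 36 were higher, with regions holding none of the other 7 factors still left out. The logistic model called 29 pairs higher, 4 lower and 3 neither, and 4 of the 11 pairs lower by stratification were higher in it. Simulated lists sharing only general occupancy reached 1.84 when stratified and 1.86 in the logistic model, and 13 pairs had intervals above those ranges in both models. Another 13 pairs had intervals below them in both, among them JunB-KLF4, which was called higher. The ranges came from a single simulated draw, and JunB-RXR, with a lower stratified limit of 1.86, lay at their edge. The ranges also rest on the chosen simulation settings, which were not matched to the observed numbers of factors per region. The counts of pairs above and below them hold for these settings alone.

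Pairs of a KLF factor and a nuclear receptor were among those called higher. Besides KLF5-RXR, the stratified odds ratio was 5.39 for KLF5-VDR (4.82 to 6.04), 4.45 for KLF4-RXR (4.01 to 4.94) and 4.42 for KLF4-VDR (3.92 to 4.98). The logistic odds ratios were 2.94, 2.51 and 2.81, and with lists of equal length the stratified values were 1.76, 3.08 and 3.20. VDR sites shared with RXR carried KLF4 or KLF5 in 83.6% of cases, against 39.3% for VDR sites without RXR, a difference of 44.3 points (95% jackknife interval 42.8 to 45.9). Of the VDR sites without RXR, 42.2% had no other factor at all. KLF5 sites shared with KLF4 carried both receptors in 68.8% of cases, against 24.7% without KLF4, a difference of 44.0 points (42.7 to 45.4). These differences were not adjusted for the number of factors at the sites. They belong to 8 differences of shares, all chosen after the data were examined.

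**Figure D3:**
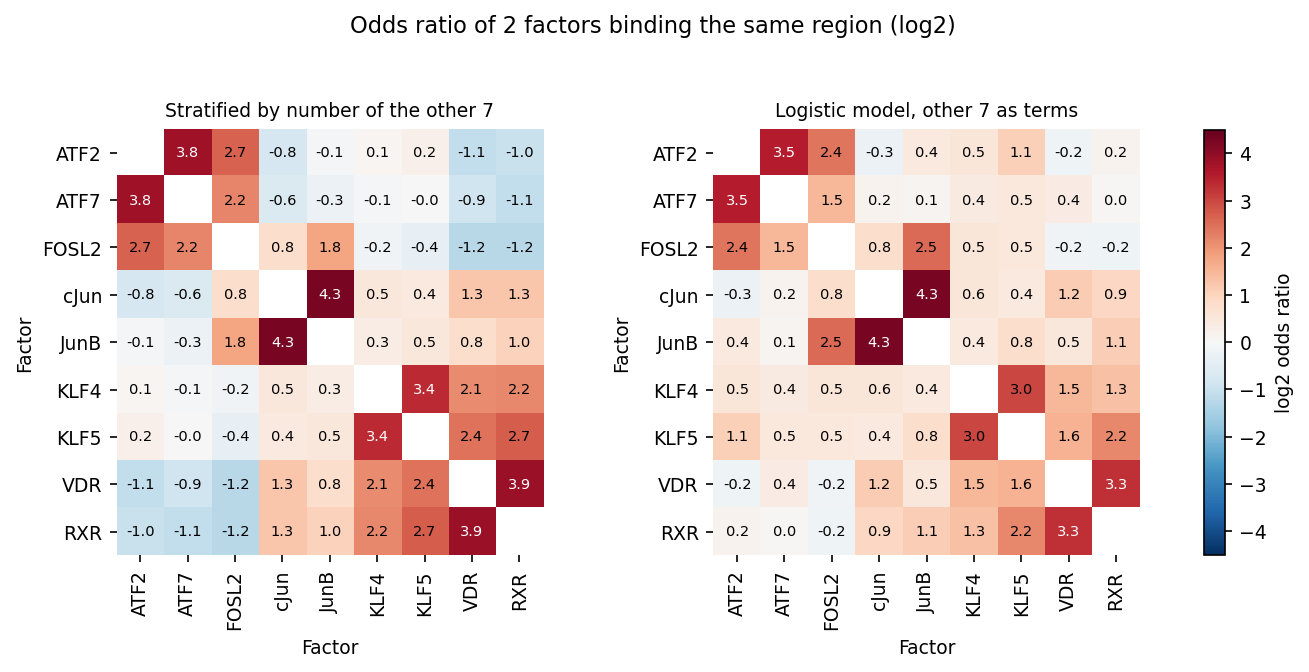
Log2 odds ratios of 36 pairs of factors, stratified by the number of the other 7 factors bound (left) and from a logistic model with the other 7 as separate terms (right); both axes list the factors, and red is above 0. The darkest red cells are cJun-JunB, VDR-RXR, ATF2-ATF7 and KLF4-KLF5 in both panels, and of the 11 pairs called lower in the left panel, 4 are lower, 4 higher and 3 neither in the right panel.

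FOSL2 shared sites with ATF factors as well as with AP-1 subunits. Its odds ratio was 6.34 with ATF2 (5.63 to 7.14), 4.63 with ATF7 (3.94 to 5.43), 3.43 with JunB (2.77 to 4.25) and 1.73 with cJun (1.51 to 1.98). The value for cJun lay within the range of simulated lists with only general occupancy in common. In the logistic model, the odds ratio was 5.85 with JunB (4.86 to 7.05), 5.27 with ATF2 (4.56 to 6.10), 2.79 with ATF7 (2.43 to 3.20) and 1.74 with cJun (1.58 to 1.91). With lists of equal length, the stratified value was 4.75 with ATF7, 3.65 with ATF2, 2.48 with JunB and 2.22 with cJun. The order of the partners thus changed with the model and with the thinning of the lists. ATF2 was listed at 53.8% of FOSL2 sites, JunB at 52.1%, ATF7 at 39.7% and cJun at 32.2%. The shares with ATF2 and JunB were not told apart (difference 1.66 points, 95% jackknife interval -4.29 to 7.60), and the share with ATF2 exceeded that with cJun by 21.6 points (17.9 to 25.2). The ATF2 list was the longer one. With lists of equal length the share with ATF2 was 27.2% and that with cJun 30.7% (difference -3.52 points, -7.09 to 0.0419). Thinning a list at random lowers the share with it in proportion to the sites removed, and ATF2 lost far more than cJun. The changed sign thus follows from the thinning and cannot decide between the partners. Neither cJun nor JunB was listed at 46.5% of FOSL2 sites, and 24.7% had none of the other 4 bZIP factors.

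The 5 lowest stratified odds ratios all joined FOSL2, ATF2 or ATF7 with a nuclear receptor. They were 0.423 for FOSL2-RXR (0.363 to 0.493), 0.424 for FOSL2-VDR (0.381 to 0.473), 0.459 for ATF2-VDR (0.420 to 0.501), 0.465 for ATF7-RXR (0.410 to 0.529) and 0.501 for ATF2-RXR (0.449 to 0.558). All 5 were below 1 on 20 of 20 chromosomes. The logistic odds ratios were nearer to 1: 0.879 for FOSL2-RXR (0.791 to 0.977), 0.891 for FOSL2-VDR (0.815 to 0.974), 0.871 for ATF2-VDR (0.801 to 0.947), 1.03 for ATF7-RXR (0.896 to 1.18) and 1.12 for ATF2-RXR (1.00 to 1.26). Against an odds ratio of 1, 4 pairs, those 3 and ATF2-cJun, were lower in both models. Against the simulated ranges, all 5 lay below in both models. Without stratification, but still leaving out regions with none of the other 7 factors, all 5 pairs were above 1. Over all regions, ATF2 sites shared less with VDR and RXR than in any reassigned draw. Because no common interval lacks a listed factor, the construction alone can give this, and it does not show avoidance. With lists of equal length the stratified odds ratios of these 5 pairs rose to between 0.777 (ATF2-RXR) and 0.911 (FOSL2-RXR), of which FOSL2-RXR no longer passed the threshold. The remaining pair of this kind, ATF7-VDR, was lower when stratified (0.542, 0.482 to 0.609) but higher in the logistic model (1.30, 1.19 to 1.43).

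Pairs within a DNA-binding family had a mean log2 odds ratio of 1.75 over 12 pairs, against 0.36 over 24 pairs between families. The difference of 1.39 was matched or exceeded by 12 of 378 assignments of the factors to families (exact permutation p = 0.0317, one-sided). With ATF2 and ATF7 as a family apart from cJun, FOSL2 and JunB, the means were 2.98 and 0.39, a difference of 2.59 (2 of 1260 assignments, exact permutation p = 0.00159, one-sided). The first result did not pass 0.05 without the FOSL2 list (difference 1.23, exact permutation p = 0.0714) or without the VDR list (0.92, exact permutation p = 0.0536). It also did not pass with unadjusted odds ratios (0.91, exact permutation p = 0.0661) or the Jaccard index (3.00 percentage points, exact permutation p = 0.161). In the logistic model it passed, with a difference of 1.15 (exact permutation p = 0.00529). With lists of equal length it passed, at a smaller difference of 0.68 (exact permutation p = 0.0212).

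The title also names super-enhancers, stretches of closely spaced active regions, and the last comparison asked whether hotspots lay near each other. Joining hotspots within 10 kb gave 697 clusters of 2 or more, against 486 ± 18.2 (SD of 1000 draws) for equal numbers of sites drawn at random from the common set. This was 1.43-fold higher (permutation p = 0.001, one-sided, the smallest that 1000 draws can give). The clusters held 1587 hotspots, and 569 of them had only 2. With lists of equal length there were 140 clusters. The largest held 12 hotspots, where random draws gave a mean of 6.82 and up to 15 (permutation p = 0.015, one-sided), and lay on chromosome 10 from 107337145 to 107388899 (mm9). Next were chromosome 10 from 116630482 to 116648371 with 9 hotspots, chromosome 10 from 116581274 to 116589518 with 7, chromosome 10 from 107052648 to 107075986 with 7, and chromosome 19 from 5840456 to 5848544 with 6. The 4 clusters on chromosome 10 lay in 2 of 3 blocks where sites of every list were dense. The cluster on chromosome 19 spanned 10 regions, and KLF4 and VDR were listed at all 10 of them, ATF2 and KLF5 at 7 each, and cJun at 1.

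The dense blocks on chromosome 10 ran from 106700001 to 107900000, from 116200001 to 116800000 and from 117200001 to 118100000 (mm9). They held 943 regions (2.72%) in 2700 kb, at 37.4, 32.0 and 33.6 regions per 100 kb. The flanking 500 kb on either side held 1.00, 2.22 and 2.33. The ATF2, ATF7 or FOSL2 list covered 82.8% of block regions, against 46.7% elsewhere, and 7.11% of all FOSL2 sites lay in the blocks. The blocks held 136 hotspots, 2.42% of the total. Without them, the largest cluster had 6 hotspots, and JunB was listed at 54.6% and ATF2 at 53.7% of FOSL2 sites (difference -0.977 points, 95% jackknife interval -3.90 to 1.95).

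**Figure D4:**
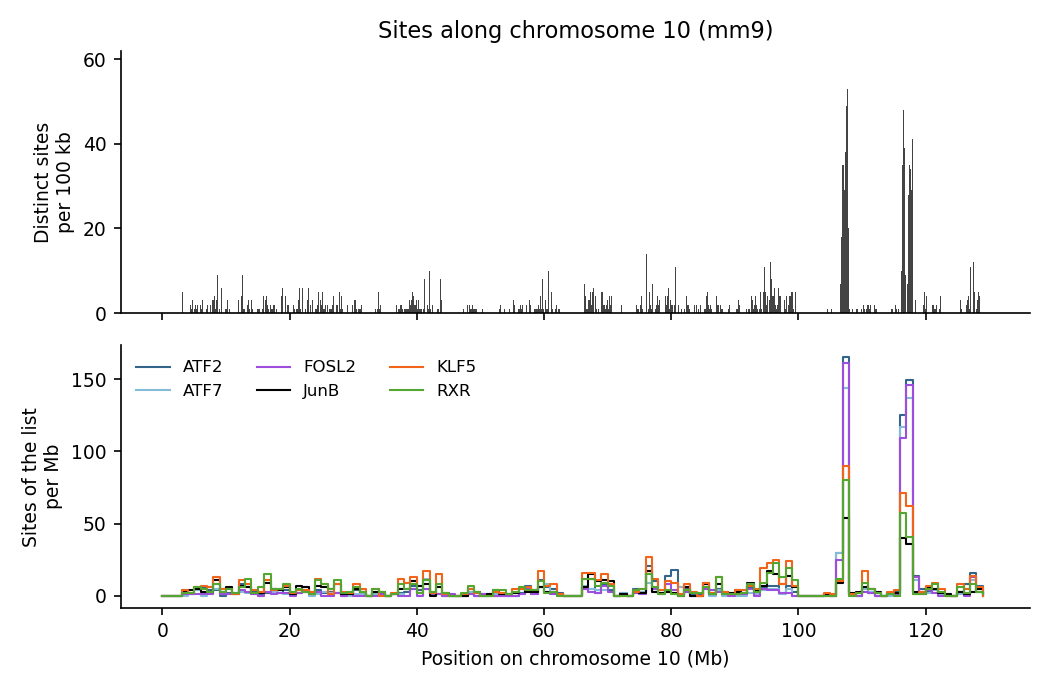
Distinct sites per 100 kb (top) and sites of 6 of the lists per Mb (bottom) along chromosome 10 (position in Mb, mm9). The 3 dense blocks stand far above the rest of the chromosome, and the ATF2, ATF7 and FOSL2 lists rise highest there.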

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

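Leaving aside 20 values that the construction of the lists fixes, 51 of the values that answer a comparison kept their direction and their side of the threshold, or, for a count, stayed within 1.5-fold of it, 8 moved and 4 no longer passed the threshold; of the values for single pairs or clusters, 80 held, 2 moved, 7 reversed and 1 no longer passed. Windows of 100 bp and an overlap of at least 50% leave shares, hotspots and odds ratios as they are by construction. Midpoints of different intervals lie at least 201 bp apart, so these settings say nothing about stability. The narrower window lengthens the gaps between hotspots and gave 696 clusters. The counts above include values with every chromosome, a setting that added only 4 list entries and so says little about stability. Equal list lengths by random draw gave 1964 hotspots, 140 clusters, a median share of 23.6%, 6 pairs called lower, at most 5 hotspots in a cluster and a family difference of 0.68. Fewer sites lower the first 3 by construction. Log2 odds ratios fell to 2.58 for cJun-JunB, 2.37 for ATF2-ATF7, 1.55 for VDR-RXR, 1.25 for KLF4-KLF5 and 0.90 for KLF5-RXR. Random removal of sites can itself lower an odds ratio. Requiring 6 or more factors gave 3605 hotspots, and requiring 4 or more gave 8378, just within the 1.5-fold limit. Leaving out each list gave 3848 (KLF5) to 5045 (ATF7). Unadjusted odds ratios, which still left out regions with none of the other 7 factors, called 36 pairs higher and 0 lower. The logistic model called 4 lower. Among the regions so kept, unadjusted log2 odds ratios reversed to 1.07 for FOSL2-RXR, 0.96 for FOSL2-VDR, 0.34 for ATF2-VDR, 0.54 for ATF7-RXR and 0.47 for ATF2-RXR. The logistic model gave 0.040 for ATF7-RXR and 0.17 for ATF2-RXR. The family difference was 0.91 with unadjusted odds ratios, 3.00 percentage points with the Jaccard index, 1.23 without the FOSL2 list and 0.92 without the VDR list; the cause was not tested, though a left-out list also leaves fewer assignments. Results without the dense blocks and the family differences with unadjusted and with logistic odds ratios were added after the data were examined. No paired analysis was possible because each factor had 1 list, and samples with replicate numbers were not used here. The better-scoring part of each list, the top 1% left out, peak strength, motif content, genes near hotspots and a family test of distances were planned and not run, for lack of scores, of an mm9 genome and annotation, or of distances other than 0 bp. The unknown depth limits every comparison between lists: a site not listed for a factor is not shown to be unbound.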

Other observations

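The combinations of factors, the odds ratio without the dense blocks and the fall of occupancy with row position were chosen after their values were seen, and the tests of copy gain were chosen after the blocks were seen. Among 1616 regions with 6 factors, 1 of 84 possible combinations made up 42.1% (95% exact interval 39.7 to 44.6): cJun, JunB, KLF4, KLF5, VDR and RXR, at 681 regions. Random reassignment of sites among the common intervals gave a mean of 1.78% for it, and lists of equal length gave 7.32%. Smaller parts of this set were frequent as well. KLF5, VDR and RXR together made up 25.3% (24.0 to 26.7) of 4350 regions with 3 factors, and KLF4, KLF5, VDR and RXR made up 20.4% (18.9 to 21.9) of 2755 regions with 4. KLF5, RXR and VDR had the 3 longest lists. Reassignment, which keeps list lengths, gave means of 4.69% and 1.67% and at most 5.39% and 2.28%, below the observed sizes. Lists of equal length gave 3.44% and 3.86%. Removing sites at random breaks up combinations that hold these lists, so this fall says nothing on its own about list length. The same holds for the 7.32% above. Among 6948 regions with 2 factors, ATF2 with ATF7 was the most frequent pair with 1317 (reassigned mean 2.26% of such regions), followed by VDR with RXR at 746 (10.7%, reassigned mean 4.42%).

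Outside the dense blocks, the clusters after that on chromosome 19 held 5 hotspots each. They lay on chromosome 17 from 71069330 to 71103226, chromosome 2 from 164198465 to 164212154, chromosome 6 from 12398962 to 12409081 and chromosome 6 from 31011992 to 31032234 (mm9). The X chromosome held 0.764% of FOSL2 sites (95% exact interval 0.564 to 1.01), 0.976% of ATF7 sites (0.765 to 1.23), 1.10% of ATF2 sites (0.918 to 1.31), 1.48% of KLF4 sites (1.19 to 1.82), 1.59% of cJun sites (1.29 to 1.93), 1.68% of KLF5 sites (1.49 to 1.89), 1.75% of JunB sites (1.50 to 2.02), 1.96% of RXR sites (1.72 to 2.22) and 2.09% of VDR sites (1.84 to 2.37).

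The dense blocks on chromosome 10 may reflect a gain of DNA copies in these cells, since extra copies give more reads in every library. The blocks were chosen for their density, so blocks were found again from 8 lists, and sites listed for the remaining factor alone were counted in them. Such sites were 123-fold denser than on the rest of chromosome 10 for FOSL2 (exact 95% interval 85.9 to 178) and 43.7-fold for ATF2 (33.8 to 56.5), but 1.75-fold for JunB (0.352 to 5.29, from 3 sites in the blocks and 79 outside), which leaves a rise in every list open. If the order of sites in the lists follows read numbers, block sites should stand nearer the top than other sites with as many factors. They did in all 9 lists, with a median percentile of at most 34.0, where 50 would be no shift. Since shared sites stand in the same order in every list, the 9 lists are not independent here. Copy gain and real clustering of binding both stay open, as no library of unprecipitated DNA was used here.

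The overlap of the ATF2, ATF7 and FOSL2 lists could come from the dense blocks or from weak background sites common to the 3 libraries. Without the blocks the odds ratio was 6.28 for ATF2-FOSL2, 4.39 for ATF7-FOSL2 and 14.2 for ATF2-ATF7, against 6.34, 4.63 and 14.2 with them, which argues against the blocks. Among 9759 regions bound by 3 or more of the 6 remaining factors the ATF2-FOSL2 odds ratio, not adjusted for occupancy, was 11.4 (95% jackknife interval 10.0 to 13.0). Background sites outside regulatory regions were predicted to give 1 or less. The overlap was thus not confined to regions with few other factors. The value cannot decide on background sites, because general occupancy alone also gives odds ratios above 1. Listing for 3 or more factors also does not show a region to be regulatory. Background sites, joint binding of these bZIP proteins, as dimers or at neighbouring sites, and an antibody that recognises more than 1 of them all stay open. Neither joint binding nor such an antibody was tested.

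The identical order of shared sites in all 9 lists may rank the sites by a signal common to the lists. The number of other factors fell with position in every list, with Spearman's rho across sites, which are not independent replicates, between -0.552 for ATF2 and -0.708 for cJun. With the order and many sites in common, the 9 lists are not independent either. The first 10% of the cJun list had a mean of 6.29 other factors and the last 10% had 1.04. An order by a summed signal over the factors is a candidate explanation; the signal itself was not used here, and no biological explanation was tested.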
